A study of Mus musculus with 12 samples.

How the data were processed

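ATAC-seq was performed on sorted mouse CD4 T cells of 2 genotypes and 6 states, with 1 library for each of the 12 groups. Per the labels' protocols, nuclei were prepared by an Omni-ATAC procedure and libraries were sequenced as single-end reads of 50 bp. Cultured Tregs received 50 ng/mL IL-6 with anti-CD3/CD28 beads for 24, 48 or 72 h. All 12 labels describe the experiment as in vivo, while the protocols describe culture for 8 of them; the state of each library was taken from its cell type, time and protocol. Per the submitters' processing notes, Bowtie2 2.3.3.1, SAMtools 1.6, Picard, deepTools, bedtools, DESeq2 and MACS2 2.1.0 were used with genome build mm10, without a stated role for each.

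The deposited files are 12 peak lists, called on each library separately, with 1 row per summit. Per the file layout of MACS2 lists as deposited, each row gives the interval, a score, the fold over background at the summit (a ratio), the −log10 p-value, the −log10 q-value and the offset of the summit. The deposited score is 10 times the −log10 p-value rounded down. All rows had a q-value of at most 0.01, as tested on the files, and lay on chromosomes 1 to 19 or X. Rows that shared an interval were joined into 1 peak that kept its best summit. Read counts were not used here, so no count model was fitted.

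Depth was recovered from the lists. The fold of a row equals (k + 1)/(λ + 1), and its −log10 p-value is that of a Poisson variable of mean λ exceeding k, for a whole number of reads k at the summit. A whole k was found for 100% of rows in every library (tolerance 0.005 in −log10 p). The most frequent λ is the background pileup, from 0.31 reads in Ptpn2+/- Tregs at 72 h to 0.771 in Ptpn2+/+ Tregs at 24 h. The smallest summit that was called held from 4 to 6 reads and did not follow the background alone. It was 5 reads in Ptpn2+/+ Tregs at 48 h (background 0.668) and 6 in Ptpn2+/+ Th17 cells (background 0.598). The background pileup also scales with the fragment length that the caller used, which is not recorded. The smallest peak, 86 to 101 bp wide, varied little.

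Peaks of all libraries were merged into 127626 union regions (median 247 bp), and a region counted as present where a peak overlapped it by at least 1 bp. Gene positions came from the RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10. Peaks were counted in each locus, the gene body with 10 kb on each side, for 21629 genes, and changes were computed on log2(peaks + 1), a scale that understates changes at low numbers. The annotation gives no strand, so the planned window of 1 kb around transcription start sites was replaced by 1 kb around either annotated end of a protein-coding gene. The planned comparison of sequence motifs was not made, because a genome sequence was not used here.

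Genotype was tested with an exact two-sided sign-flip permutation test over the 6 states, whose smallest p is 0.0312, and cultured against ex vivo libraries with an exact two-sided permutation test over all 495 splits. Other comparisons of states have no test. They were made within each genotype, and the number of regions specific to 1 side in both genotypes is given beside n1 × n2/N, the overlap of independent lists among the N regions peaked in a compared library. Percentages of regions carry exact Clopper-Pearson 95% intervals. For each of 18 gene lists (253 genes, all found), the mean change was placed among 10000 random lists of the same size, matched in 20 bins of mean locus peaks, with limits at percentiles 2.5 and 97.5. Some genes belong to more than 1 list (14 pairs of lists share genes). The random lists make no allowance for list genes that lie close together and share locus peaks, so percentiles of such lists are approximate.

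The tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule takes 13 fixed genes (Ptpn2, Foxp3, Rorc, Il17a, Il17f, Il23r, Ccr6, Il2ra, Ctla4, Ikzf2, Il6ra, Stat3, Socs3). It adds, per comparison, up to 10 list genes each way with the largest change relative to the median gene. It also adds 5 genes each way among all protein-coding genes with at least 5 locus peaks in a compared library. A gene had to move the same way in both genotypes, or in at least 5 of 6 states. For genotype-consistent regions it takes the nearest genes. Alternatives were computed for every gene of the rule, of which the text names some.

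Alternatives were a stricter threshold (−log10 q of at least 5), equal-length lists (the 18675 peaks of each library with the highest −log10 p), autosomes, coverage of at least 50% of a region, union regions from windows of 250 bp around summits, flanks of 50 kb, gene ends with 1 kb in place of the locus, a 2.5 kb gene-end window, other minimum numbers of states, and each state left out. Chosen after seeing the data were a floor of 20 times the background at the summit and the covered length of a locus in units of 250 bp, the last because wide peaks merge. Floors of 15, 20, 25, 30 and 40 had been looked at before 20 was kept. Over these the mean log2 ratio of peaks by genotype was 0.28, 0.41, 0.57, 0.65 and 0.99, with exact permutation p = 0.281, 0.125, 0.0625, 0.0312 and 0.0625, so the floor decides whether the test passes 0.05.

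The steps were tested on simulated data. Of 200 regions planted per comparison, 200 were recovered for Th17 against Treg, for exTreg against Treg and for genotype, among 127553 simulated regions. The planted regions had a peak in every library of 1 side and in none of the other. Their recovery therefore tests the counting steps, and not whether peaks are missed through depth or threshold. Random gene lists, drawn from the same genes as the lists they were placed among, fell past the limits in 6%, 4.2% and 4.2% of draws for those comparisons, over 21629 genes. The background pileup was recovered in 5 simulated libraries. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.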

Results

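Chromatin accessibility was measured by ATAC-seq in CD4 T cells of BALB/c mice that carry the SKG background and a FoxP3-eGFP reporter, a green fluorescent mark of regulatory T cells (Tregs). The design crossed 2 Ptpn2 genotypes, Ptpn2+/+ and Ptpn2+/-, with 6 cell states. Ptpn2 encodes a protein tyrosine phosphatase that restrains cytokine signalling through JAK and STAT proteins. Tregs and Th17 cells were taken directly from spleen and lymph nodes (ex vivo), and Tregs were also cultured with IL-6 and anti-CD3/CD28 beads for 24, 48 or 72 h. The cells that had lost FoxP3-eGFP after 72 h were collected separately as exTregs. Each of the 12 groups had 1 library, so no comparison between 2 groups had a replicate. The deposited lists held between 18675 peaks, in Ptpn2+/+ Tregs ex vivo, and 91638 peaks, in Ptpn2+/+ Tregs at 48 h. The sequencing depth was read from the background pileup, the number of reads expected by the peak caller at a position outside peaks, which ran from 0.31 to 0.771 reads. Coordinates are on mm10.

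The targeted gene, Ptpn2, had an accessible region at its end of higher coordinate (chromosome 18, 67724090 to 67725686) in all 12 libraries. The fold over background at its best summit ran from 7.07 in Ptpn2+/+ Th17 cells to 10.7 in Ptpn2+/+ exTregs, and was 8.17 against 7.55 in Ptpn2+/- and Ptpn2+/+ Tregs ex vivo. Peak lists do not show whether 1 allele is missing, so they do not check the genotype labels. A second Ptpn2 region (chromosome 18, 67699490 to 67699945) had a peak in all 8 cultured libraries and in none of the 4 ex vivo libraries, with folds between 11.5 and 16.3; it was chosen after its values were seen.

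Cell state separated the cultured libraries more than genotype did, and the ex vivo libraries less clearly. The overlap of 2 lists was expressed as the Jaccard index, the shared regions divided by all regions of either list, over 127626 merged regions. For 11 of the 12 libraries the nearest other library was the same cell state of the other genotype. The exception was Ptpn2+/- Tregs ex vivo, nearest to Ptpn2+/- Th17 cells ex vivo at 0.576. In Ptpn2+/+ the index of Tregs with Th17 cells ex vivo was 0.5385, little below the 0.5565 of ex vivo Tregs across genotypes. Same-state pairs had indices from 0.557 for Tregs ex vivo to 0.73 for Tregs at 24 h. Ex vivo and cultured libraries had indices between 0.192 and 0.427, which the longer cultured lists hold down, since 90.7% to 98.2% of the regions of each ex vivo library had a peak in each cultured library. A core of 12241 regions had a peak in every library.

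The cultured libraries held far more peaks than the ex vivo libraries. The 8 cultured libraries held 64455 to 91638 peaks and the 4 ex vivo libraries 18675 to 31621, a difference of 1.65 on the log2 scale or 3.14-fold (exact two-sided permutation test over 495 splits, p = 0.002, n = 8 and 4). The covered length was 3.51-fold greater, at 19 to 29.5 Mb against 5 to 8.81 Mb (exact permutation test, p = 0.002). The gain lay mostly away from gene ends, since the share of peaks within 1 kb of an annotated end of a protein-coding gene was 22.2% to 27.4% in culture and 38.3% to 48.5% ex vivo. The background pileup did not separate the groups (difference −0.08 on the log2 scale, exact permutation test, p = 0.752). The enrichment over background at the 12241 regions peaked in every library was 2.4-fold higher in culture (exact permutation test, p = 0.002). States from the same animals are not shown to be independent, and this holds for all tests over libraries.

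**Figure D1:**
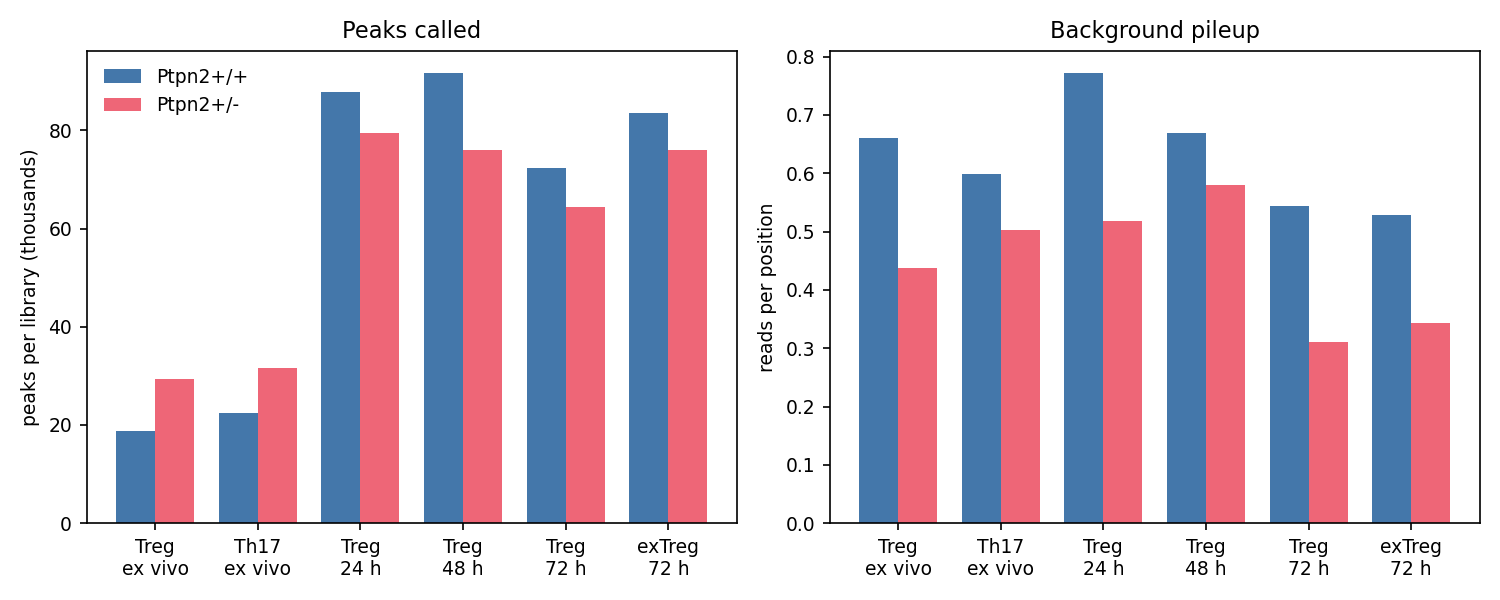
Number of peaks (left) and background pileup (reads per position, right) in each of the 12 libraries, by cell state, with Ptpn2+/+ in blue and Ptpn2+/- in red. The 8 cultured libraries held 64455 to 91638 peaks and the 4 ex vivo libraries 18675 to 31621, and the background was lower in Ptpn2+/- in all 6 states.

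Th17 cells and Tregs taken ex vivo differed at several of the genes that define them. Peaks were counted in each gene's locus, the gene body with 10 kb on each side. Il17a, the gene of the signature Th17 cytokine, had 4 locus peaks in Ptpn2+/+ and 5 in Ptpn2+/- Th17 cells and none in either Treg library. Rorc, which encodes the Th17 master regulator RORγt, had 3 and 5 against none, and Il23r, the IL-23 receptor, had 2 and 2 against none. The widest gain was at the IL-1 receptor gene Il1r1, with 8 and 11 peaks against none (log2 change of peaks + 1 of 3.38 ± 0.29, SD over the 2 genotypes). Ccr6, the chemokine receptor used to sort the Th17 cells, had 3 and 4 peaks against 1 and 1. On the Treg side, Ikzf2, the gene of the Treg factor Helios, had 5 and 12 peaks in Tregs and 2 and 3 in Th17 cells (−1.35 ± 0.50). Lrrc32, which encodes the TGF-β docking receptor GARP, had 2 and 2 peaks against none, and Gpr83 had 1 and 2 against none. Foxp3 itself had 3 and 2 locus peaks in Tregs and 2 and 1 in Th17 cells. Il2ra went the other way, with more peaked regions in Th17 cells than in Tregs in both genotypes. Its region at 11635004 to 11636483 on chromosome 2 had higher folds in Tregs (8.32 and 8.66) than in Th17 cells (4.36 and 4.50). Another, at 11657660 to 11658005, was peaked in both Th17 libraries (5.27 and 5.18) and in neither Treg library. Outside the lists, Map1b had 3 and 6 peaks in Th17 cells against none in Tregs. Cnksr3 (3 and 6), Itgb8 (3 and 5) and Swap70 (4 and 8) had peaks in Tregs and at most 1 in a Th17 library.

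As a group, 13 of the 21 Th17 program genes had more locus peaks in Th17 cells in both genotypes and 0 had fewer. The list's mean change of 0.98 stood at percentile 100 of 10000 random lists matched on mean locus peaks. The Treg identity list lay at percentile 0.01 with a mean of −0.25, with 10 of 24 genes lower and 2 higher in both genotypes. By the mean over the genotypes the split was closer, with 13 genes lower, 10 higher and 1 equal. With peaks of −log10 q of at least 5 the Treg identity list lay at percentile 11.1. The IL-6 and STAT3 signalling list lay at percentile 0.36, with Tyk2 at 2 and 4 peaks in Tregs and 1 and 1 in Th17 cells. The list of CD8 T cell and NK cell genes, which the sort should exclude in part through its CD8-negative gate, lay at percentile 99.99, with Klrd1 at 3 and 3 peaks in Th17 cells against none and Klrb1c at 2 and 2 against none; within 1 kb of gene ends it lay at 15.5. The erythroid list lay at percentile 0.925 through Gata1, with 2 and 2 peaks in Tregs and none in Th17 cells, and turned within 1 kb of gene ends (percentile 71.4). By region, 2302 regions were peaked in Th17 cells and not in Tregs in both genotypes, out of 6973 in Ptpn2+/+ and 8125 in Ptpn2+/-, where independent lists would share 1561. In the other direction 1095 regions were Treg-only in both genotypes, against 679.7. With the stricter threshold these counts were 1205 and 490.

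Cultured Tregs had more peaks at several effector loci than ex vivo Tregs, beyond the general gain. Il1r1 had no peak in either ex vivo Treg library and 12 to 18 peaks in the 6 cultured Treg libraries. Il12rb2, a subunit of the IL-12 receptor, had none ex vivo and 9 to 13 in culture. Tbx21, which encodes the Th1 factor T-bet, had none ex vivo and 4 to 6 in culture, Rorc none and 5 to 8, and Il23r none and 4 to 8. The median gene with a peak gained 0.96 on the log2 scale of peaks + 1, and the following changes are relative to it: 3.03 ± 0.38 for Il1r1, 2.64 ± 0.19 for Il12rb2, 1.90 ± 0.05 for Rorc and 1.69 ± 0.22 for Tbx21 (SD over the 2 genotypes). Il23r gained 1.67 ± 0.42, but its change was −0.10 within 1 kb of its gene ends. Itgam gained 2.35 ± 0.06 and, outside the lists, Csgalnact1 gained 2.88 ± 0.20 and Tgfbr3 gained 2.81 ± 0.99. Foxp3 had 3 and 2 peaks ex vivo and 5 to 11 in culture. The Th17 program list stood at percentile 99.99, although at 90.3 within 1 kb of gene ends. The Th1 program list stood at 99.79 (95.2 with equal-length lists, the 18675 strongest peaks of each library). The B cell list (99.48) and the CD8 T and NK cell list (98.57) lay above the upper limit too, and both fell inside the limits with equal-length lists, at 92.2 and 73.5. The lists of pan T cell genes (0.04), IL-6 and STAT3 signalling (0.87) and housekeeping genes (0.95) gained less than their matched random lists. Within 1 kb of gene ends the pan T cell list turned (60.5) and the IL-6 and STAT3 list lay at 26.7, and with equal-length lists the housekeeping list lay at 6.76. Socs3, a feedback brake on JAK and STAT3, kept 3 to 5 peaks in culture against 4 and 4 ex vivo, so that it lagged the median gene (−1.08 ± 0.47). Duxf3 had 8 and 3 peaks ex vivo, LOC100504180 had 7 and 3 and Gm4981 had 5 and 3, against at most 1 in culture; these 3 genes belong to repeated families, so their peaks are uncertain.

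By region, 17422 regions were absent ex vivo and present at all 3 culture times in both genotypes, and 20 were lost in the same sense, where independent lists would share 6457 and 2.72. With equal-length lists the split was 837 gained and 762 lost. Lists of equal length balance gains and losses by construction, so these counts do not show what the excess of gains rests on.

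Over the culture, the Treg lists were shorter at 72 h than at 24 h, at 72338 against 87778 peaks in Ptpn2+/+ and 64455 against 79452 in Ptpn2+/-. The 48 h list was the longest in Ptpn2+/+ (91638) and lay between the others in Ptpn2+/- (76003). Of the 24 h regions, 69.3% (exact 95% binomial interval 69 to 69.7) still had a peak at 72 h in Ptpn2+/+ and 68% (67.6 to 68.3) in Ptpn2+/-. Such intervals cover counting error only. In both genotypes 10380 regions were lost and 1688 gained, where independent lists would share 5787 and 672. A further 1024 were lost in Ptpn2+/+ and gained in Ptpn2+/-, and 881 were gained in Ptpn2+/+ and lost in Ptpn2+/-. With equal-length lists 1458 were lost and 1107 gained in both genotypes. Ikzf2 went from 38 and 36 peaks at 24 h to 27 and 20 at 48 h and 19 and 19 at 72 h, but turned within 1 kb of its gene ends (0.29). Socs1, another brake on cytokine signalling, went from 8 and 6 peaks to 3 and 2, Irf8 from 7 and 10 to 4 and 3, and Il2 from 4 and 4 to 2 and 1. Lef1, a factor of resting T cells, went from 36 and 31 to 21 and 14. Outside the lists, Epc2 went from 13 and 13 to 3 and 3, and Zcchc7 from 7 and 7 to 2 and 1. In the other direction, Ryk went from 1 and 1 to 7 and 4, Ankrd33b from 2 and 1 to 7 and 5, and Pax5 from 5 and 4 to 9 and 8. The resting T cell list lay lowest, at percentile 0.1, with 13 of 15 genes lower in both genotypes. The lists of T cell receptor activation (1.14), follicular helper T cells (1.62) and IL-2 and STAT5 signalling (1.76) followed. With equal-length lists the direction turned for these 4 lists, with the resting T cell list at 99.8 and the T cell receptor list at 99.3, and for Lef1 (1.16) and Socs1 (0.29). Pax5 (−0.58) turned as well. The 24 h libraries also had the highest background pileup of each genotype's cultured Tregs except Ptpn2+/- at 48 h. Thinned to the lowest ex vivo background, the Ptpn2+/+ Treg lists held 77467, 78425 and 67697 peaks at 24, 48 and 72 h. The Ptpn2+/- list at 72 h already had a lower background, so it has no such value.

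ExTregs differed from the FoxP3-positive Tregs of the same 72 h cultures at Treg and Th17 loci, the comparison that addresses the loss of FoxP3. Ikzf2 had 7 and 6 peaks in exTregs against 19 and 19 in Tregs (−1.42 ± 0.14). Its strongest region in these Tregs (chromosome 1, 69544169 to 69544633) stayed peaked in exTregs, with folds of 12.3 and 13.5 against 8.54 and 9.39. A region at 69555485 to 69556097 went the other way, from 5.53 and 5.09 in Tregs to 3.93 and no peak in exTregs. The lower count thus does not mean that the whole locus closed. Lrrc32 had 4 and 3 against 7 and 6, Gpr83 3 and 4 against 6 and 7, and Klrg1 1 and 1 against 3 and 4. Ccl20, which encodes the ligand of CCR6, had 3 and 2 peaks against none (1.79 ± 0.29). Il17f had 3 and 4 against 1 and 0, Il17a 8 and 5 against 3 and 3, and Il23r 7 and 11 against 4 and 5. Rorc was already open in the FoxP3-positive cells, with 8 and 5 peaks against 5 and 4 in exTregs (−0.42 ± 0.23), a direction that turned with the stricter threshold (0.16). Foxp3 had 5 and 7 locus peaks in exTregs and 6 and 6 in Tregs, and Ctla4 had 8 and 6 against 10 and 8, turning to 0.11 with the stricter threshold and 0.29 with equal-length lists. Il2ra, Il6ra, Stat3, Socs3 and Ccr6 did not move the same way in both genotypes. Other gains were at Mcm6 (8 and 8 against 4 and 3) and Il2rg (10 and 7 against 4 and 4), which turned with equal-length lists (−0.29 and −0.42). Outside the lists, Robo1 gained from 0 and 0 to 6 and 6, Slc4a4 from 1 and 2 to 16 and 15 and Kbtbd12 from 0 and 0 to 4 and 5. Cyp4f18 was lower at 2 and 2 against 8 and 7, and Zbp1 at 1 and 1 against 5 and 4.

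The positions of the Foxp3 peaks differed between Tregs and exTregs although their number was alike. A region within the gene (chromosome X, 7583824 to 7584440) had a peak in all 8 Treg libraries, ex vivo and cultured, with folds between 4.03 and 5.67, and in no Th17 or exTreg library; with the stricter threshold and with equal-length lists 0 regions of the gene kept this pattern. A further region within the gene (chromosome X, 7593352 to 7594575) was peaked in all 6 cultured Treg libraries, with folds from 4.72 to 7.22, and in no other library. A region at 7580389 to 7580549 was peaked in both exTreg libraries alone, with folds of 5.29 and 5.13. At Il17a, a region upstream in coordinate (chromosome 1, 20725643 to 20725905) was peaked in both Th17 and both exTreg libraries and in none of the 8 Treg libraries. It was the 1 such region at the loci of the Th17 program, and with the stricter threshold 0 regions there had this pattern. With equal-length lists 2 regions there had it, and whether the Il17a region was among them was not examined. These regions were chosen after their values were seen, at genes fixed in advance.

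**Figure D2:**
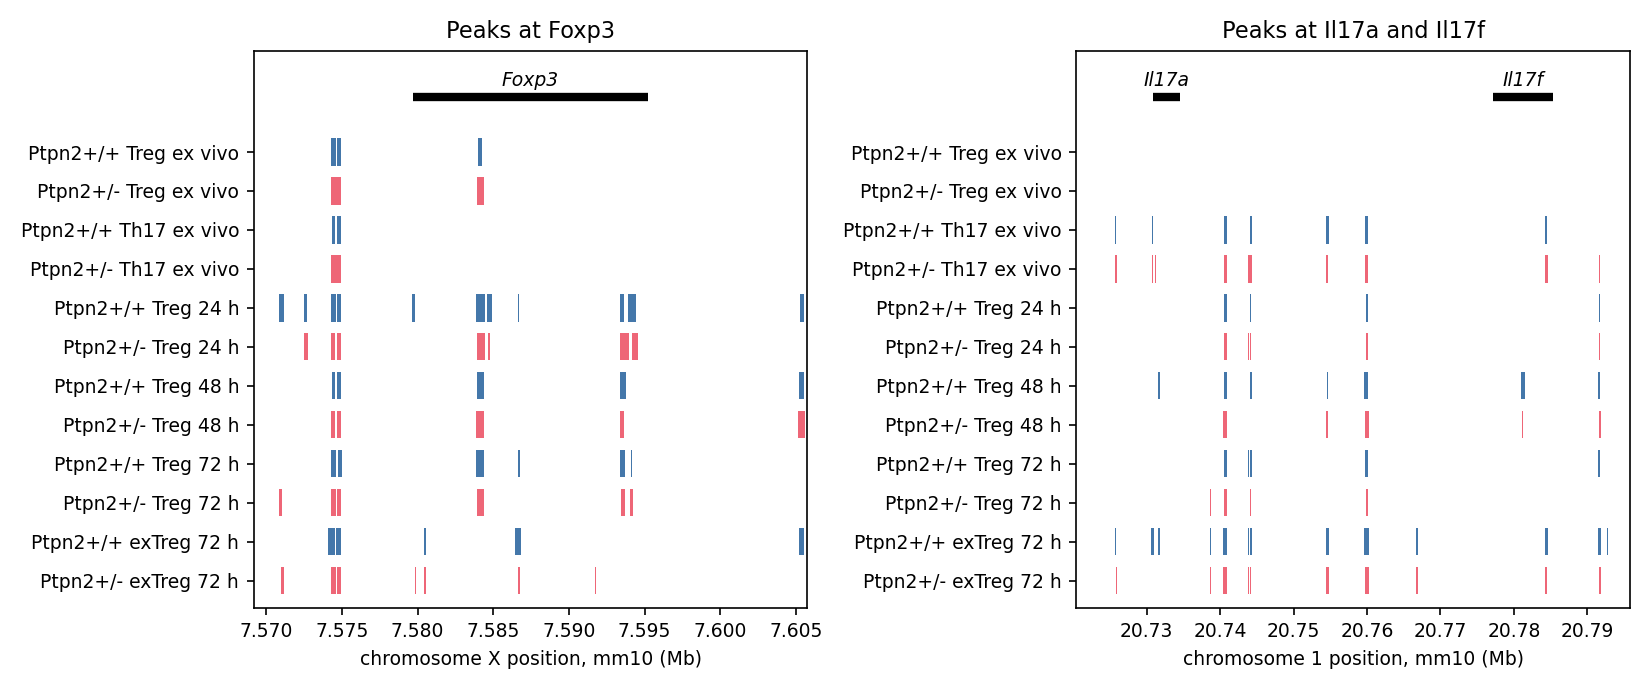
Peaks of each library (bars, Ptpn2+/+ in blue and Ptpn2+/- in red) along Foxp3 (left) and Il17a and Il17f (right), with genes as black bars and the position on mm10 in Mb on the horizontal axis. The region at 7583824 to 7584440 within Foxp3 was peaked in the 8 Treg libraries and absent from the Th17 and exTreg libraries in the lists as deposited, though not under stricter settings, and the 2 ex vivo Treg libraries had no peak in the Il17a and Il17f window.

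As a group, 10 of the 24 Treg identity genes had fewer locus peaks in exTregs in both genotypes and 1 had more, and the list's mean of −0.24 stood at percentile 0. With equal-length lists the mean lay at percentile 52.9, and with the stricter threshold at 0. Of the 21 Th17 program genes 9 had more peaks in both genotypes and 1 had fewer, at percentile 99.39, and at 99.98 with equal-length lists; within 1 kb of gene ends it was 89.4. The Th1 program list lay at percentile 0.04, but at 8.94 with the stricter threshold and 21.4 with equal-length lists. The B cell list, with 3 genes lower in both genotypes (Cd79b at 1 and 1 peaks against 4 and 3) and 3 higher (Blnk at 9 and 7 against 5 and 4), lay at 1.86, and the erythroid list, with Gata1 at 0 and 1 against 2 and 2, at 0.29. Both moved to the middle of the random lists with equal-length lists, at 71.4 and 68.5. In both genotypes 6535 regions were gained and 2592 lost in exTregs, where independent lists would share 4155 and 1073. The genotypes went opposite ways at other regions. Of these, 1010 were gained in Ptpn2+/+ and lost in Ptpn2+/-, and 1178 were lost in Ptpn2+/+ and gained in Ptpn2+/-. With equal-length lists the regions gained and lost in both genotypes were 1538 and 1421, and with the stricter threshold 4011 were gained.

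**Figure D3:**
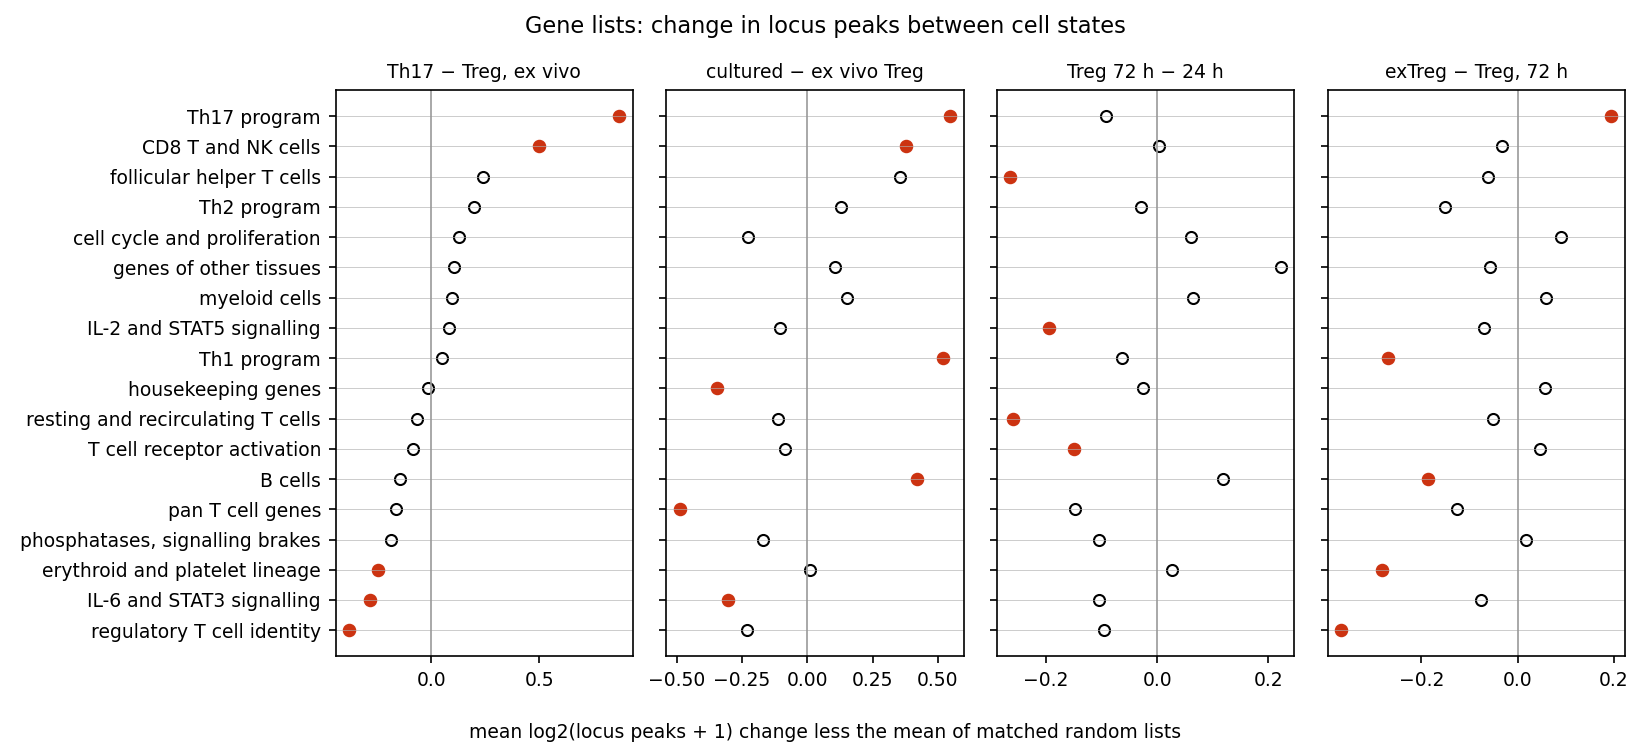
Mean change in log2(locus peaks + 1) of each of 18 gene lists less the mean of 10000 matched random lists, for 4 comparisons of cell states; filled red points lie past the limits and open points inside them. The Th17 program list lay above the upper limit in 3 of the 4 panels, and the Treg identity list below the lower limit for Th17 against Treg and exTreg against Treg, the last not with equal-length lists (percentile 52.9).

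Ex vivo Treg-only regions were less often open in exTregs than in Tregs at 72 h in both genotypes. Th17-only regions were more often open, with intervals that did not overlap in Ptpn2+/- alone. Most of both sets were open in every cultured library. In Ptpn2+/+, 79.6% (exact 95% binomial interval 78.3 to 80.9) of 3993 Treg-only regions had a peak in Tregs at 72 h and 74.4% (73 to 75.7) in exTregs, while the share of 6973 Th17-only regions was 84.3% (83.4 to 85.1) and 84.7% (83.8 to 85.5). In Ptpn2+/-, 81.3% (80.3 to 82.3) of 6176 Treg-only regions had a peak in Tregs at 72 h and 74.1% (73 to 75.2) in exTregs, while the share of 8125 Th17-only regions went from 71.2% (70.2 to 72.2) to 75.7% (74.7 to 76.6). The balance of Th17-only over Treg-only regions therefore differed by 5.64 percentage points between exTregs and Tregs in Ptpn2+/+ and by 11.7 in Ptpn2+/-, with counting errors of 1.12 and 1.02. These errors treat the shares as independent, although exTregs and Tregs were scored on the same regions, so they are approximate. With equal-length lists the shift was 9.94 and 14 points. Over all regions, exTregs overlapped less with ex vivo Th17 cells than Tregs at 72 h did, with Jaccard indices of 0.245 against 0.282 in Ptpn2+/+ and 0.368 against 0.427 in Ptpn2+/-; the exTreg lists were the longer ones. The share of Th17 regions peaked was 94% in exTregs and 94.2% in Tregs at 72 h in Ptpn2+/+, and 91.2% and 90.7% in Ptpn2+/-. Whether the genotypes differ in it was not tested, since each has 1 library per state. Within the FoxP3-positive Tregs, the Treg-only share was 91% at 24 h and 81.3% at 72 h in Ptpn2+/- and 82.6% and 79.6% in Ptpn2+/+. The Th17-only share was lower at 72 h too, by −4.1 points in Ptpn2+/- and −0.66 in Ptpn2+/+, so the 75.7% of Ptpn2+/- exTregs lay near the 75.3% of Tregs at 24 h. Regions peaked in both ex vivo cell types had a lower share in exTregs than in Tregs at 72 h as well, by −1.23 and −0.50 points.

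**Figure D4:**
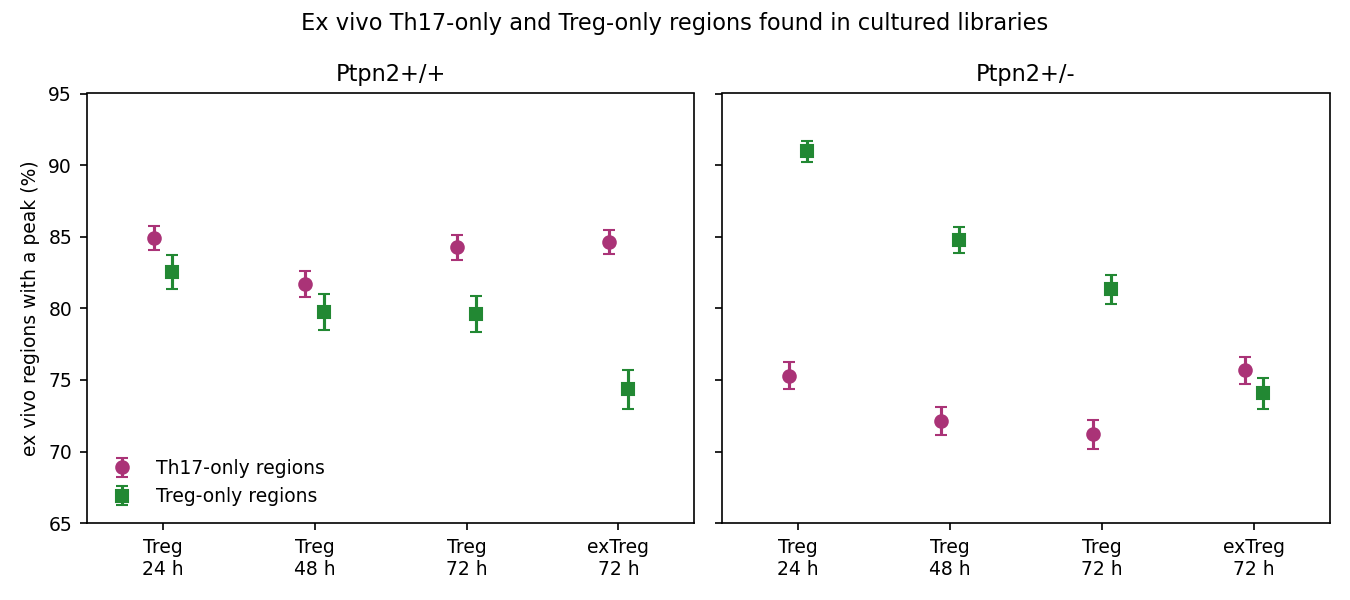
Percent of the ex vivo Th17-only regions (purple circles) and Treg-only regions (green squares) with a peak in each cultured library, for Ptpn2+/+ (left) and Ptpn2+/- (right), with exact 95% binomial intervals; the axis starts at 65%. Treg-only regions were less often open in exTregs than in Tregs at 72 h, at 74.4% against 79.6% in Ptpn2+/+ and 74.1% against 81.3% in Ptpn2+/-.

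Genotype was compared within each of the 6 states, and no difference was detected in the number, the covered length or the gene-end share of peaks, while background and enrichment differed in all 6 states. Itk, the gene of a T cell receptor kinase, had fewer locus peaks in Ptpn2+/- in 6 of 6 states (−0.17 ± 0.15 on the log2 scale relative to the median gene, SD over states), as did Rab31 (−0.73 ± 0.72) and Gpr4 (−0.70 ± 0.18). Cd3d and Cd3g were lower in 5 of 6 states (−0.39 ± 0.54 and −0.29 ± 0.40) with 10 kb flanks, and near 0 with 50 kb flanks. Rel (−0.31 ± 0.26) was lower in 5 states. Polr2a was higher in 6 of 6 states (0.36 ± 0.15), and Dusp6 (0.49 ± 0.56), Tnfrsf1b (0.38 ± 0.35), Cebpb (0.36 ± 0.47) and Stat6 (0.33 ± 0.33) in 5; Tnfrsf1b turned with equal-length lists (−0.0594) and Dusp6 within 1 kb of gene ends (−0.12). Over all genes gains were large at Fhl2 (0.87 ± 1.12) and at Sav1 (0.82 ± 0.66, above the median gene in 6 of 6 states), the last turning with the stricter threshold (−0.0155). Ptpn2 itself had a mean change of −0.39 ± 0.41, lower than the median gene in 4 states and higher in 0. Foxp3 (−0.17 ± 0.42), Rorc (−0.12 ± 0.41) and Stat3 (−0.22 ± 0.34) moved in mixed directions. None of these genes has a test of its own. All but the fixed genes were picked for moving the same way in at least 5 of 6 states, which some genes do by chance. How many genes chance would give was not computed, so the named genes do not show a genotype pattern. Few list genes passed this rule. The most in a list were 4 of 21 higher and 0 lower (IL-6 and STAT3 signalling) and 3 of 14 lower and 0 higher (pan T cell genes).

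Of the 18 lists, the pan T cell list lay at percentile 0.18 of its matched random lists and the myeloid list at 1.24, both lower in Ptpn2+/-. With equal-length lists they lay at 7.86 and 9.13, inside the limits. Of the 14 pan T cell genes, 10 had a lower mean in Ptpn2+/- and 4 a higher one. Only 3 were below the median gene in at least 5 states (Itk, Cd3d and Cd3g), and 0 above it. Cd3d and Cd3g may share peaks through their flanks and so may not count as separate genes, which the random lists do not allow for. Cd3d and Cd3g, both on that list, turned with 50 kb flanks and with covered length.

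The share of a library's peaks that lay in each of the 18 gene lists gave no adjusted p under 0.562 (exact sign-flip permutation tests over 6 states, Benjamini-Hochberg over the lists). The smallest unadjusted value was that of the myeloid list, lower in Ptpn2+/- in 6 of 6 states by a mean of −0.0079 percentage points (exact test, p = 0.0312, the smallest that 6 pairs allow). The number of peaks differed by a mean of 0.07 ± 0.39 on the log2 scale (SD, n = 6 states, exact two-sided sign-flip permutation test, p = 0.656), higher in Ptpn2+/- in 2 states. With floors on the summit, looked at after seeing the data, this mean depended on the floor. At 20 times the background it was 0.41, higher in 5 states (exact permutation test, p = 0.125). At 30 times it was 0.65, higher in 6 states (exact permutation test, p = 0.0312). The covered length differed by 0.03 ± 0.45 (exact permutation test, p = 0.906) and the share of peaks near gene ends by −1.3 ± 4.83 percentage points (exact permutation test, p = 0.531). The background pileup was lower in Ptpn2+/- in all 6 states, by −0.51 ± 0.23 (exact permutation test, p = 0.0312), so depth moved with genotype. The enrichment over that background at the 12241 regions peaked in every library was higher in Ptpn2+/- in all 6 states, by 0.48 ± 0.37 (exact permutation test, p = 0.0312). Only 3 regions had a peak in at least 5 more states of 1 genotype than of the other. A region in Poli (chromosome 18, 70520577 to 70521179) was peaked in 6 Ptpn2+/- and 1 Ptpn2+/+ libraries, with a median fold of 8.07. A region in Frs2 (chromosome 10, 117110378 to 117110631) was peaked in 6 Ptpn2+/+ and 1 Ptpn2+/- libraries. The last, on chromosome 4 (3090086 to 3090312), lay 81770 bp from the nearest gene, Vmn1r2. Of the 32 ways to assign the genotype labels within states, 15 gave at least as many regions.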

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

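All tests of explanations in this part were chosen after the results were seen.

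In the lists as deposited, the difference in peak number between genotypes pointed opposite ways before and after culture. Ptpn2+/- libraries held more peaks in both ex vivo states (29269 against 18675 in Tregs, 31621 against 22448 in Th17 cells) and fewer in all 4 cultured states (64455 against 72338 in Tregs at 72 h, for example). The opposition did not hold with the floor of 20 times the background, where Ptpn2+/- held more peaks in 5 of 6 states. Among cultured states these were Tregs at 24 h (54867 against 52936), Tregs at 72 h (50008 against 48181) and exTregs (59011 against 54506). At 48 h Ptpn2+/- held fewer (46192 against 49029). The floor is a multiple of each library's own background, which was lower in Ptpn2+/-. For the lists as deposited, the mean log2 ratio was 0.57 ex vivo and −0.18 in culture, a difference of −0.75 that was not tested. Depth can be excluded as the source of the ex vivo part, because the background pileup of the Ptpn2+/- libraries was lower there (mean log2 ratio −0.42) while their lists were longer. Signal over background could account for the ex vivo part, as the enrichment at regions peaked in all 12 libraries was higher in Ptpn2+/- in both ex vivo states (mean log2 ratio 0.89). It was also higher in all 4 cultured states (mean 0.27), where Ptpn2+/- held fewer peaks, so it does not by itself set the direction. The genotype itself, or the preparation of single libraries, stays open as the origin of the ex vivo part. For the cultured part depth and genotype cannot be told apart, because thinning the Ptpn2+/+ summits to the Ptpn2+/- background left a mean log2 ratio of −0.0693 ± 0.0996 (SD, n = 4 states), within its spread of 0 but below 0 in 3 of the 4 states.

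The covered length showed the same opposition, with a difference of −0.86 on the log2 scale between cultured and ex vivo states, and so did the share of peaks near gene ends, with 9.19 percentage points; neither difference was tested. The share of peaks at proliferation genes was lower in Ptpn2+/- in both ex vivo states and higher in all 4 cultured states, a difference of 0.0315 percentage points that was not tested; among the 18 lists some such pattern can arise by chance.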

How the results depend on the processing

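The floor of 20 times the background and the covered length of a locus were chosen after seeing the data, after other floors had been looked at. The greater number of peaks in culture kept its direction and its p under the stricter threshold, autosomes alone and the floor of 20 (equal-length lists fix it). The Th17 program list for Th17 against Treg stayed past its limit under all 5 alternatives run for it. No alternative brought a genotype test to 0.05, though a floor of 30 that had been looked at gave an exact permutation p = 0.0312. The motif comparison and its alternatives were not run, as a genome sequence was not used here. Unless a construction is named, the cause was not tested. Lists carry fewer regions under the stricter threshold and equal-length settings by construction, and depth limits weak peaks most.

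By genotype, equal-length lists turned the covered length (−0.0107) and the share near gene ends (0.10 points). Leaving out 1 state, the number of peaks ranged from −0.0439 to 0.14, the covered length from −0.10 to 0.10 and the share from −1.98 to 0.20 points, so their directions are not settled. Genotype-consistent regions numbered 14 with equal-length lists, 6 from summit windows of 250 bp, 0 for 6 states against 0, 186 for at least 4 more states, and 10 to 176 with 1 state left out at that minimum.

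With the stricter threshold, regions shared by both genotypes were 1205 (Th17-only), 490 (Treg-only), 7 (lost in culture), 4011 (gained in exTregs) and 643 (gained from 24 to 72 h), and 67.3% (Ptpn2+/+) and 64.5% (Ptpn2+/-) of 24 h regions were kept. With equal-length lists they were 837 (gained in culture), 762 (lost in culture), 1538 and 1421 (gained and lost in exTregs), 1107 and 1458 (gained and lost from 24 to 72 h), with 80.1% and 78.8% kept and Th17 shifts of 9.94 and 14 points. With 50% of a region covered, Treg-only regions were 500, 56.9% and 50.9% of 24 h regions were kept, and the Ptpn2+/- shift was 14.2 points. From summit windows 73.2% and 71.4% were kept.

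The number of lists past the limits was 3 for Th17 against Treg, 3 for exTreg against Treg and 1 for genotype with the stricter threshold. It was 2 for 72 against 24 h with equal-length lists. With 50 kb flanks it was 4 for culture, 7 for 72 against 24 h and 1 for genotype. Within 1 kb of gene ends it was 2 for 72 against 24 h, 2 for exTreg against Treg and 15 in all, and with covered length 1 for genotype.

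Lists past the limits that turned are given as the mean less that of the random lists. With the stricter threshold it was the erythroid list in exTregs (0.0153). With equal-length lists, from 24 to 72 h, they were IL-2 and STAT5 (0.17), T cell receptor activation (0.17), resting T cells (0.26) and follicular helper T cells (0.0637), and in exTregs Treg identity (0.0056), B cells (0.0616) and erythroid (0.052). With 50 kb flanks it was the B cell list in culture (−0.0437). Within 1 kb of gene ends they were the CD8 T and NK cell (−0.0615) and erythroid (0.0356) lists for Th17 against Treg, and pan T cell (0.0301) and B cell (−0.0578) in culture. Of the other list values, 41 came inside the limits, 37 went past them, 259 stayed on their side, and 100 of lists inside the limits changed sign.

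Genes of the rule that turned are given as relative log2 changes. With the stricter threshold they were Ctla4 for Th17 against Treg (0.29), Ptgdr2 from 24 to 72 h (−0.15), Ctla4 (0.11), Rorc (0.16) and Ptpn2 (−0.0294) in exTregs, and by genotype Nt5e (−0.15), Tnf (0.0452), Slc36a4 (−0.082) and Sav1 (−0.0155). With equal-length lists they were, in culture, Ikzf2 (−1.26), Il2ra (−1.59) and Il6ra (−1.39). From 24 to 72 h they were Il6ra (0.21), Ccr6 (1.00), Foxp3 (0.50), Pax5 (−0.58), Socs1 (0.29), Lef1 (1.16), Rel (0.29) and Kmt2c (1.29). In exTregs they were Ctla4 (0.29), Mcm6 (−0.29), Il2rg (−0.42) and Rad50 (0.29), and by genotype Tnfrsf1b (−0.0594), Tnf (0.39), Slc36a4 (−0.33) and Eid2b (−0.17). With 50 kb flanks they were Mcm4 from 24 to 72 h (−0.28) and by genotype Cd3d (0.022), Cd3g (0.007) and Tnf (0.11). Within 1 kb of gene ends they were, in culture, Il17a (−0.26), Il17f (−0.26), Ikzf2 (−0.33), Il2ra (−0.24), Il23r (−0.10), Ccr6 (−0.26), Ptpn2 (−0.37), Cr2 (0.0692), Klf1 (0.86) and Zfp618 (−0.26). From 24 to 72 h they were Ikzf2 (0.29) and Shank2 (−0.50), and by genotype Dusp6 (−0.12), Mcl1 (−0.17) and Jak1 (−0.0283). With covered length they were Cr2 for Th17 against Treg (0.22), Il17f (−0.13) and Ptpn2 (−0.14) in culture, Mcm4 (−0.0474) and Maf (0.14) from 24 to 72 h, Ptpn2 in exTregs (−0.12), and by genotype Cd3d (0.0541) and Cd3g (0.0677). Of the other gene values, 424 moved by less than 1 SD and 473 by more.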

Other observations

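All tests in this part were chosen after the results were seen.

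This set was thought of after the Foxp3 peaks were seen, and its count was known before a prediction was written. A small set of regions followed FoxP3 status across both genotypes and across culture. In all, 61 regions had a peak in each of the 8 FoxP3-positive Treg libraries and in none of the 4 Th17 and exTreg libraries, and 53 had the reverse pattern. The first set held the Foxp3 region at 7583824 to 7584440 on chromosome X (median fold 4.78). Its highest median fold, 11.1, was at a region 1119 bp from Gata1 on the same chromosome (7977783 to 7978302). It also held regions in Tram2 (10.7), Tox (7.21) and Foxp1 (4.48), and near Icos (101860 bp away), Ifng (15414 bp away) and Ccr7 (13005 bp away). The reverse set was led by regions in Rftn1 (9.58) and Stxbp4 (8.54) and held one 4999 bp from Il17a and one in Tmem132e (7.62). Among 100 splits of the 12 libraries into 8 and 4, 4 gave at least the real 114 regions, the real split included. With the stricter threshold it was 5 and with equal-length lists 3. The other splits were drawn at random from all such splits. They need not keep both genotypes of a state together, as the real split does, so they are not matched to it. Since the splits are unmatched, their counts lie close to 5 of 100 and the set was chosen for its pattern, they leave open whether it goes beyond chance. The highest other split gave 10577, which points to a stronger structure in the samples than FoxP3 status. With the stricter threshold and with equal-length lists 57 and 130 regions met the same definition, and the Foxp3 region was not among them, since its peaks are modest.

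The 3.14-fold longer lists of cultured cells were not a matter of depth. Thinned to the lowest ex vivo background, 8 of 8 cultured libraries kept more peaks than the longest ex vivo list of 31621. Of these, 6 were thinned, to 67697 peaks at the lowest, and 2 Ptpn2+/- libraries already had a lower background and stood at 64455 and 76058. The enrichment at the 12241 regions peaked in all libraries was higher in culture, the lowest cultured value being 1.28 times the highest ex vivo one, so a better signal over background could lengthen the lists. Activation of the cells and library quality both stay open, because no library separates them.

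Regions that differed by genotype were more frequent on chromosome 18 around Ptpn2. Within 20 Mb of the gene, 9 of the 186 regions that differed by at least 4 states were found, where the share of all regions there (1.53%) gives 2.84. Among the 32 assignments of genotype labels within states, 1 gave as many, the real one, and the highest other gave 8, while with the stricter threshold 2 of 32 gave as many. Since the settings part at 0.05 and the window was chosen after the values were seen, whether the grouping goes beyond chance stays open. Of the 9, 3 were peaked more often in Ptpn2+/-, among them those in Poli (70520577 to 70521179) and Ldlrad4 (68148288 to 68149041), and 6 more often in Ptpn2+/+, among them one in Myo5b (74763179 to 74763549). The 6 also include neighbouring regions nearest to Mex3c, between 73547505 and 73573767, which were counted separately. Of the 186, 171 were peaked more often in Ptpn2+/+, whose lists had the higher background, and 153 of these had a peak in all 4 cultured Ptpn2+/+ libraries and in no other. With 1 cultured state left out, 10 to 15 regions differed by at least 4 states. A candidate explanation is strain variants carried along with the Ptpn2 allele. Differences of at least 3, 4 and 5 states had been looked at under 3 list settings before 4 was kept. At least 3 states gave 57 regions near Ptpn2 against 52 for the highest other assignment, 46 against 46 with the stricter threshold and 21 against 19 with equal-length lists. At least 4 states gave 4 against 3 with equal-length lists. At least 5 states gave 1 against 1, 2 against 1 and 3 against 2 for the lists as deposited, stricter and of equal length. Another stretch, chromosome 17 from 20 to 40 Mb, also held 9 of the 186. It is narrower than the window of 20 Mb on each side of Ptpn2, and its share of all regions was not computed. The explanation stays undecided, since the stricter threshold gave 6 regions, no more than the highest other assignment, and sequence variants were not analysed here. For the count of 3 genotype-consistent regions, 15 of 32 assignments gave as many and the highest other gave 7, so chance cannot be excluded.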
